A study of Homo sapiens with 8 samples.

How the data were processed

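RNA from primary human retinal endothelial cells, 4 untreated samples and 4 samples treated with 1 mM carboplatin for 24 h, was hybridised to 1-colour whole-transcript arrays. Per the labels, 200 ng of RNA was taken per sample and the product was labelled with biotin. The authors deposited normalised log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA (robust multi-array average), which corrects the background, sets all arrays to 1 distribution by quantile normalization and summarises the probes of a probe set. Versions are not given in the sources used here. That the scale is log2 was inferred from the values, which lie between 3.59 and 14.9, as RMA gives. Scanner files were not used here, so background correction and probe summary were kept as the authors made them. Quantile normalization forces equal distributions before the probes are summarised, so a change in the total amount of RNA per cell is not visible in these values. The deposited distributions are not fully equal. Their 75th percentile over all probe sets lay at 8.60 to 8.66 in untreated and 8.50 to 8.57 in treated arrays. Dim probe sets give compressed fold changes.

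The deposited table holds 33297 probe sets. In the platform annotation supplied with the data, 19460 probe sets have 1 gene symbol, 1754 have several and 12083 are not listed and so are unnamed here. Symbols were updated through the Entrez gene number to NCBI RefSeq's gene table for assembly GRCh38.p14, which matched 19429 probe sets and not 31, and that table also gave gene biotypes and genomic lengths. No genome build is given for the arrays, so no coordinates are reported. XIST, TSIX and Y-linked genes (24 probe sets) were left out because the cells are primary human cells. A gene with several probe sets (768 genes) was represented by the one with the highest mean over all arrays, which left 18394 genes. No filter on dim genes was applied. No pair of arrays held identical values.

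Groups were compared with R 4.3.3 and limma 3.58.1 (lmFit and eBayes with default settings, carboplatin minus untreated, all 8 arrays, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are limma's moderated errors, and intervals are 95% intervals. Gene lists were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and adjustment over 27 lists, and also with an estimated correlation and with fry. The lists covered p53 targets, cytokines and chemokines, leukocyte adhesion, DNA replication, mitosis, NF-kB feedback, interferon-stimulated genes, replication-dependent histones, crosslink and excision repair, pro-apoptotic and anti-apoptotic genes, endothelial identity, Notch and sprouting angiogenesis, coagulation with fibrinolysis and vascular tone, the blood-retina barrier, platinum transport and thiols, NRF2 targets, integrated stress and unfolded protein responses, heat shock, immediate early genes, TGF-beta and matrix, metalloproteinases, cholesterol synthesis, and markers of mural cells and fibroblasts, of retinal glia, neurons and pigment epithelium, of leukocytes and of lymphatic endothelium.

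The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups, leaving out symbols of small nucleolar RNAs that begin with SNOR, microRNAs, LOC and LINC genes, RNU, RNY and RN7 genes and olfactory receptors, the 2 members of each list with the largest absolute change whatever their p, and always CDKN1A, MDM2, CXCL8, IL6, CCL2, ICAM1, VCAM1 and SELE. Genes named outside this rule are marked as named after their values were seen.

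The alternatives were quantile normalization of the tested genes again, cyclic loess, scaling to each array's 75th percentile over the tested genes or to the median of probe sets without a symbol, filters at the 25th percentile or the median of signal, eBayes with trend and robust, array weights, the sample number as a block, the mean of a gene's probe sets, leaving out each sample in turn, limma's treat against a log2 fold change of 1, and the 2 other list tests. A restriction to protein-coding genes was added after seeing the data. The fit was tested on simulated data for 18394 genes in 4 arrays each, drawn with the spread of the real genes. It recovered 14% of 50 genes changed by a log2 fold change of 0.25, 76% at 0.5, 94% at 1 and 100% at 2, and called 10 of 18111 unchanged genes. Of 3 lists shifted by 0.5, 3 were recovered, and 1 of 24 unshifted lists was called. Few genes were changed in the simulation, whereas 52.0% of the real genes passed, so its recovery rates are not those of the real comparison. Simulated genes were also drawn independently of one another. The simulation therefore cannot test the preset correlation or give the rate of false list calls in the real data. The result of 1 gene family is not reported here.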

Results

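Messenger RNA and other transcripts were measured on 8 whole-transcript microarrays hybridised with RNA from primary human retinal endothelial cells, the cells that line the blood vessels of the retina. Of these, 4 samples came from untreated cells and 4 from cells exposed for 24 h to 1 mM carboplatin, a platinum drug that crosslinks DNA and is used against cancers including retinoblastoma. Each array received 200 ng of RNA. Values are the authors' normalised log2 values, and each array's median lay between 7.39 and 7.45. Across the 18394 tested genes, arrays of untreated cells correlated with one another at Pearson's r of 0.992 to 0.996. Arrays of treated cells correlated at 0.986 to 0.992, against 0.906 to 0.936 between the groups. The first principal component, which separated the groups, held 85.8% of the variance. The labels describe the 4 samples of a group as separate dishes and name no separate donors, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, with a median standard error of 0.088 on the log2 scale. Detection calls were not used here. Of 338 olfactory receptor genes, which endothelium is not expected to express, 95% had means under 7.51 without and 7.73 with the drug, a limit chosen after the data were seen. A change whose lower mean lies under these values, as in 27 of the 69 genes named by the rule, is read as a lower bound and given as at least that size. Where both means lie under them, the levels are called dim and given in place of a size.

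The comparison asked how a day of carboplatin changed the transcripts of retinal endothelium, a question tied to the vascular side effects of the drug when it is delivered to the eye. Treated cells had far less RNA for TNFSF10, the death ligand TRAIL, which fell from 10.71 ± 0.02 to 6.67 ± 0.30 (log2 value, mean ± SD, n = 4 each), at least a 16.5-fold lower level. CCL2, a chemokine that attracts monocytes, was 13.9-fold lower, at 12.43 ± 0.15 without and 8.63 ± 0.42 with the drug. ID2, an inhibitor of helix-loop-helix transcription factors, rose at least 13.1-fold, from 7.33 ± 0.08 to 11.04 ± 0.14, and PMAIP1, which encodes the pro-apoptotic protein NOXA, rose 10.2-fold. Genes of endothelial identity, of Notch and sprouting angiogenesis, of leukocyte adhesion and of mitosis fell as groups, while p53 target genes, DNA replication genes and immediate early genes rose as groups. All 7 calls, made with camera's preset correlation, were lost with an estimated correlation, at an adjusted p = 0.197 to an adjusted p = 0.457.

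The rule for named genes left out small nucleolar RNAs with SNOR symbols, some of which rose by more than the genes given here. Within that rule, CST1, a secreted cystatin that inhibits cysteine proteases, rose 6.03-fold. TOB1, an antiproliferative regulator, rose 5.63-fold, and HEXIM1, an inhibitor of the transcription elongation factor P-TEFb, rose 5.60-fold. Other small RNAs outside messenger RNA were also among the large rises. VTRNA1-1, a vault RNA, rose at least 10.4-fold, and the small Cajal body RNA SCARNA4 rose at least 10.4-fold. RPPH1, the RNA part of ribonuclease P, rose 7.09-fold from 10.25 ± 0.20 to 13.08 ± 0.16. The other large falls were those of EXOC6, a subunit of the exocyst (9.62-fold), ARHGAP18 (9.54-fold), BMP4, a bone morphogenetic protein (at least 8.88-fold), and the scaffold gene FRMD4B (8.82-fold). EDN1, which encodes the vasoconstrictor endothelin-1, was 8.73-fold lower, and KIT, the receptor for stem cell factor, was at least 8.73-fold lower. The adjusted p-values of these 16 genes in limma with Benjamini-Hochberg adjustment lay between 7.28e-13 and 2.88e-10, and in each of them the values of the groups did not overlap.

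Across 18394 genes, 9567 (52.0%) passed an adjusted p of 0.05 in limma. The calls comprised 4684 higher and 4883 lower genes. Larger changes leaned downward, with 300 genes at least 2-fold higher against 1452 at least 2-fold lower, and 50 against 171 at 4-fold. Among the 300 higher genes, 173 were protein-coding and 100 were small nucleolar or small nuclear RNAs, whereas 1430 of the 1452 lower genes were protein-coding. The values of the groups were fully separate in 8848 genes (48.1%), where chance gives 2.86%. The split of the calls depended on the scaling: 49.0% of calls were upward as deposited, 73.4% when each array was set to its own 75th percentile over the tested genes, which moved the median fold change by 0.19 on the log2 scale, and 36.9% when arrays were set to the median of probe sets without a gene symbol.

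Genes activated by the tumour suppressor p53 rose as a group. Of 31 measured members, 19 were higher, 5 were lower and 7 did not pass, and adjusted over the list alone 20 were higher and 7 lower. CDKN1A, the cell cycle inhibitor p21, rose by a log2 fold change of 1.28 ± 0.10 (SE), and GDF15, a secreted stress cytokine, rose by 2.15 ± 0.08, next to the 3.35 ± 0.09 of PMAIP1. MDM2, the ubiquitin ligase that limits p53, fell by 0.61 ± 0.09 on the log2 scale (adjusted p = 3.22e-05), from 11.64 ± 0.17 to 11.03 ± 0.07. The list's median log2 fold change was 0.32, and limma's camera, which compares a list with all other genes, gave an adjusted p of 6.12e-04 with its preset correlation. The call was lost at an adjusted p = 0.381 with an estimated correlation. With that setting camera called 0 of the 27 lists, with a smallest adjusted p of 0.197 and 5 lists at an unadjusted p under 0.05. The size of the correlation alone does not account for these losses. Leukocyte markers had an estimated correlation of 0.0103, close to the preset 0.01, yet went from a camera adjusted p of 6.77e-03 to 0.197. By contrast fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 23.

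Genes of cell death and of DNA repair moved both ways, as did all 18394 tested genes, with 4684 higher and 4883 lower. In the pro-apoptotic list, 6 of 18 members were higher, 5 lower and 7 not past, the same counts of 6 and 5 adjusted over the list alone. CYCS, which encodes cytochrome c, rose by 1.41 ± 0.10 alongside PMAIP1. In the anti-apoptotic list, 2 of 7 members were higher, 3 lower and 2 not past, with the same 2 and 3 adjusted over the list alone. BCL2A1, an antagonist of apoptosis, rose between dim levels, from 6.47 ± 0.17 to 7.61 ± 0.04, and CFLAR, an inhibitor of caspase-8, had a log2 fold change of -0.90 ± 0.10. Neither list was called (camera, adjusted p = 0.585 and 0.772). Their medians of 0.03 and 0.01 turned to -0.03 and -0.05 when arrays were scaled to the probe sets without a symbol, and the mean of the anti-apoptotic list was -0.09. Crosslink and nucleotide excision repair genes had 7 of 28 members higher, 11 lower and 10 not past, also 7 and 11 adjusted over the list alone. REV3L and REV1, which encode parts of the translesion synthesis machinery, fell by at least 1.2 on the log2 scale. The repair list's median of -0.11, which became 0.08 with 75th percentile scaling, was not called (camera, adjusted p = 0.221).

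Genes of DNA replication and genes of mitosis moved in opposite directions. In the replication list, 21 of 34 members were higher, 2 lower and 11 not past, and 22 and 2 adjusted over the list alone. PCNA, the sliding clamp of DNA polymerases, rose by 1.33 ± 0.09, and MCM4, a subunit of the replicative helicase, rose by 0.89 ± 0.09. In the mitosis list, 3 of 29 members were higher, 18 lower and 8 not past, with the same 3 and 18 adjusted over the list alone. DLGAP5, a spindle protein, fell by at least 1.22 on the log2 scale and TOP2A, the type II topoisomerase of dividing cells, by at least 1.11. The 3 higher members, named after their values were seen, were HMMR, dim at 6.64 without and 7.39 with the drug, UBE2C at 0.38 and BIRC5 at 0.37. The medians were 0.39 for replication and -0.60 for mitosis, each with a camera adjusted p of 4.92e-04 that rose to an adjusted p = 0.457 and 0.450 with an estimated correlation. Among genes above the median signal the mitosis call was also lost, at an adjusted p of 0.109.

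Histone genes, whose transcripts mostly lack poly(A) tails and accompany DNA replication, were lower as a group. In this list 5 of 44 members were higher, 25 lower and 14 not past, and 5 and 26 adjusted over the list alone. The linker histone gene H1-4 changed by -2.17 ± 0.13 and H2BC14 by -2.14 ± 0.15. The median was -0.33 (camera, adjusted p = 1.94e-03, and adjusted p = 0.503 with an estimated correlation), and the call was also lost among genes above the median signal, at an adjusted p of 0.0510. Histone genes are near-identical copies, so the value of each single gene is uncertain.

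Cytokines and chemokines did not rise as a group. Of 25 measured members, 8 were higher, 5 lower and 12 not past, with the same 8 and 5 adjusted over the list alone. CXCL8, the neutrophil chemokine interleukin-8, rose 1.85-fold from 9.25 ± 0.24 to 10.14 ± 0.20 (adjusted p = 1.47e-05), whereas CCL2 fell as given above and CXCL11, an interferon-induced chemokine, was lower, at 7.46 ± 0.08 without and 6.02 ± 0.30 with the drug, both dim levels. IL6, dim in both groups, did not pass, with a difference of log2 values of -0.13 (95% interval -0.33 to 0.07, adjusted p = 0.249), which cannot bound a change in its RNA, and its level lay at the 23.8 percentile of all genes. The list's median was 0.15 and its mean -0.11, and camera gave an upward direction with an adjusted p of 0.623, while fry gave a downward direction with an adjusted p of 0.327.

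Genes listed as leukocyte adhesion molecules fell as a group. Of 14 members, 1 was higher, 9 were lower and 4 did not pass, with the same 1 and 9 adjusted over the list alone. CD34, a sialomucin, fell by at least 2.22 on the log2 scale and ALCAM, an immunoglobulin-type adhesion molecule, changed by -1.69 ± 0.12. SELE, which encodes E-selectin, was lower, at 7.36 ± 0.05 without and 6.62 ± 0.12 with the drug, both dim levels (adjusted p = 1.03e-06), and ICAM1 was 1.25-fold lower (adjusted p = 6.33e-03), a call that was lost at an adjusted p of 0.182 with 75th percentile scaling. VCAM1, also dim in both groups, did not pass, at -0.09 (95% interval -0.26 to 0.08, adjusted p = 0.368) and a level at the 23.3 percentile. The single higher member was CD44, the hyaluronan receptor, at 0.51, named after its value was seen. The list's median was -0.75 (camera, adjusted p = 8.45e-04, and adjusted p = 0.282 with an estimated correlation). The endothelial identity list also holds 3 of the 14 members, CD34 among them, so the falls of these lists are not independent.

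**Figure D1:**
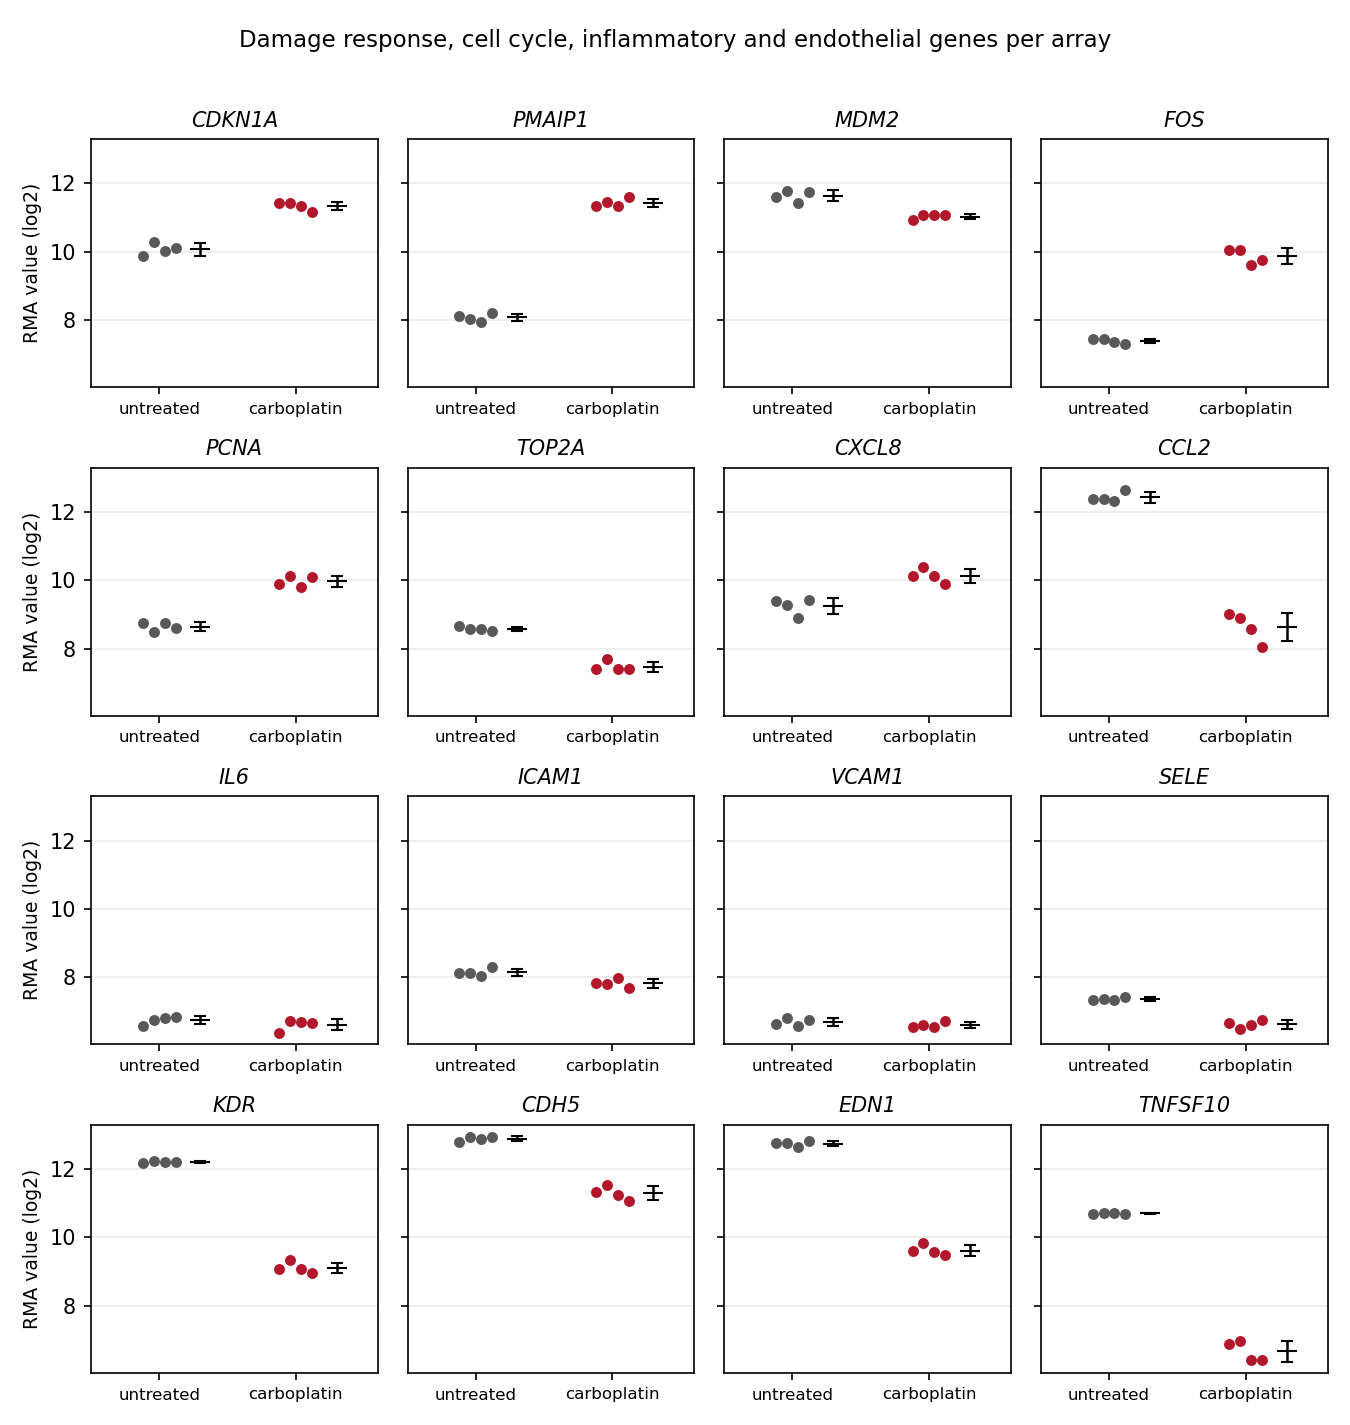
Deposited log2 value of 16 genes in each of the 4 untreated (grey) and 4 carboplatin-treated (red) samples, with the group mean and SD as bars beside the points. CDKN1A, PMAIP1, FOS, PCNA and CXCL8 were higher with carboplatin, IL6 and VCAM1 did not pass the test, and the other 9 genes were lower, with CCL2 at 12.43 ± 0.15 without and 8.63 ± 0.42 with the drug.

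Feedback genes of the NF-kB pathway and interferon-stimulated genes were not called as lists. In the NF-kB list, 6 of 16 members were higher, 3 lower and 7 not past, the same 6 and 3 adjusted over the list alone. NFKBIZ, an inducible regulator of NF-kB, rose by 1.16 ± 0.10, and NFKB1, which encodes the p105 and p50 subunit, fell by at least 1.48 on the log2 scale. In the interferon list, 9 of 22 members were higher, 4 lower and 9 not past, the same 9 and 4 adjusted over the list alone. The transcription factor gene IRF1 rose between dim levels, from 6.86 ± 0.17 to 7.55 ± 0.13, and RIGI, a sensor of viral RNA, fell by at least 1.82 on the log2 scale. The medians were 0.05, which became -0.01 with scaling to the probe sets without a symbol, and 0.10, with camera adjusted p-values of 0.623 and 0.344.

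Genes that define endothelial cells fell nearly throughout. Of 29 measured members none was higher, 27 were lower and 2 did not pass, and 28 were lower adjusted over the list alone. KDR, the main receptor for vascular endothelial growth factor, fell from 12.21 ± 0.03 to 9.11 ± 0.15, an 8.59-fold lower level, and FLI1, an ETS transcription factor of endothelium and blood, was at least 7.12-fold lower. CDH5, the adherens junction protein VE-cadherin, was 3.02-fold lower, and VWF, the von Willebrand factor, was 4.35-fold lower. The 2 members that did not pass, named after their values were seen, were NOS3 at -0.20 and AQP1, dim at 7.05 without and 6.85 with the drug. The median was -1.03 (camera, adjusted p = 6.95e-14, and adjusted p = 0.197 with an estimated correlation). In the same arrays the markers of mural cells and fibroblasts had a median of 0.10 and those of leukocytes 0.35.

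The Notch and sprouting list had 4 of 26 members higher, 14 lower and 8 not past, with the same 4 and 14 adjusted over the list alone. NRP1, a co-receptor for vascular endothelial growth factor, changed by -2.24 ± 0.08, next to KDR, which both lists hold. The 4 higher members, named after their values were seen, were ESM1 at 0.79, VEGFA at 0.49, HES1 at 0.41 and RAMP3 at 0.27. The median was -0.59 (camera, adjusted p = 4.92e-04, and adjusted p = 0.197 with an estimated correlation). Genes of coagulation, fibrinolysis and vascular tone had 2 of 22 members higher, 13 lower and 7 not past, and 3 and 13 adjusted over the list alone. EDN1 and VWF led the falls, and the 2 higher members, named after their values were seen, were PTGS2, an inducible prostaglandin synthase, at 1.82 and PLAUR, the urokinase receptor, at 0.88. The median was -0.33 (camera, adjusted p = 7.52e-03, and adjusted p = 0.363 with an estimated correlation, and 0.0510 among genes above the median signal). Blood-retina barrier genes had 5 of 20 members higher, 11 lower and 4 not past, and 6 and 11 adjusted over the list alone. TJP1, the tight junction scaffold ZO-1, changed by -1.84 ± 0.09 and CDH5 by -1.59 ± 0.10, but the list's median of -0.33 was not called by camera (adjusted p = 0.102), while fry called it lower (adjusted p = 1.79e-05).

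Immediate early genes, which cells switch on within minutes of a stimulus, were higher after 24 h. Of 25 members, 22 were higher, 2 lower and 1 not past, and 22 and 3 adjusted over the list alone. FOS rose at least 5.59-fold from 7.39 ± 0.06 to 9.87 ± 0.22 and JUNB rose 3.44-fold, both genes of the AP-1 transcription factor. The 2 lower members, named after their values were seen, were KLF6 at -0.34 and FOSL2 at -0.19. The median was 0.83 (camera, adjusted p = 1.57e-07, and adjusted p = 0.197 with an estimated correlation).

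The integrated stress and unfolded protein response list had 12 of 23 members higher, 7 lower and 4 not past, with the same 12 and 7 adjusted over the list alone. DDIT3, the stress transcription factor CHOP, rose by 1.63 ± 0.09, and HERPUD1, a protein of endoplasmic reticulum degradation, changed by -1.61 ± 0.13. The median was 0.29 (camera, adjusted p = 0.102), and the list was called with cyclic loess at an adjusted p of 0.0482. Heat shock genes had 4 of 12 members higher, 2 lower and 6 not past, again 4 and 2 adjusted over the list alone, with BAG3 at 0.59 ± 0.08 and HSPA8 at -0.42 ± 0.07, both chaperone genes (median 0.08, camera adjusted p = 0.713). NRF2 target genes had 9 of 20 members higher, 7 lower and 4 not past, and 10 and 7 adjusted over the list alone. ABCC1, an exporter of glutathione conjugates, changed by -1.49 ± 0.11 and the malic enzyme gene ME1 by -1.14 ± 0.08 (median 0.14, camera adjusted p = 0.413). Genes of platinum transport and thiols had 7 of 24 members higher, 6 lower and 11 not past, and 8 and 6 adjusted over the list alone. ATP7A, a copper exporter that can also move platinum drugs, fell by at least 1.38 on the log2 scale, next to ABCC1, and the metallothionein gene MT1X, named after its value was seen, rose by 1.23 ± 0.10 (median 0.10, camera adjusted p = 0.413).

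Genes of the TGF-beta pathway and the extracellular matrix fell as a group, with 8 of 35 members higher, 20 lower and 7 not past, and 8 and 22 adjusted over the list alone. ID2 and BMP4, given above, were the members with the largest changes, in opposite directions. The median was -0.60 (camera, adjusted p = 4.92e-04, and adjusted p = 0.363 with an estimated correlation). Matrix metalloproteinases and their inhibitors had 3 of 17 members higher, 10 lower and 4 not past, and 4 and 10 adjusted over the list alone. ADAMTS18 changed by -1.81 ± 0.10 and ADAMTS1 rose by at least 1.39, both secreted metalloproteases. The median was -0.34 (camera, adjusted p = 0.0425, and adjusted p = 0.363 with an estimated correlation), and the call was also lost without untreated sample 2 (adjusted p = 0.0667) and without untreated sample 3 (adjusted p = 0.0524). Cholesterol synthesis genes had none of 18 members higher, 13 lower and 5 not past, with the same 13 adjusted over the list alone. SQLE, squalene epoxidase, changed by -1.49 ± 0.09 and HMGCS1, which makes the precursor of mevalonate, by -1.45 ± 0.09. The median was -0.45 (camera, adjusted p = 4.92e-04, and adjusted p = 0.197 with an estimated correlation).

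Markers of other cell types were measured in the same way. Among the 338 olfactory receptor genes, used above to set the dim limits, 67 were higher and 0 lower, with a median of 0.15. Small rises of dim markers may therefore be a drift of background rather than marker RNA. Leukocyte markers rose as a list, with 7 of 11 members higher, none lower and 4 not past, also 7 adjusted over the list alone. CD68, a lysosomal protein abundant in macrophages, rose 3.01-fold from 8.53 ± 0.06 to 10.12 ± 0.17, and CD14, a co-receptor for bacterial lipopolysaccharide, rose at least 1.61-fold (list median 0.35, camera adjusted p = 6.77e-03, and adjusted p = 0.197 with an estimated correlation). Of the 11 members, 9 lay below the median signal of all genes, and among genes above it the list had an adjusted p of 0.0656. Mural cell and fibroblast markers had 4 of 16 members higher, 1 lower and 11 not past, with the same 4 and 1 adjusted over the list alone. ABCC9, a potassium channel subunit, was dim at 5.34 ± 0.19 without and 5.67 ± 0.09 with the drug, and LUM, a matrix proteoglycan, at 5.21 ± 0.15 and 4.91 ± 0.09 (list median 0.10, camera adjusted p = 0.354), and the call of LUM was lost with 75th percentile scaling. Markers of retinal glia, neurons and pigment epithelium had 8 of 18 members higher, 1 lower and 9 not past, again 8 and 1 adjusted over the list alone, with RBPMS at -0.94 ± 0.11 and GLUL, glutamine synthetase, at 0.54 ± 0.09 (list median 0.20, camera adjusted p = 0.0990). Lymphatic endothelial markers had 1 of 6 members higher, 2 lower and 3 not past, with the same 1 and 2 adjusted over the list alone. LYVE1, a hyaluronan receptor, changed by -1.04 ± 0.10 and the chemokine gene CCL21 was dim at 7.31 ± 0.05 without and 7.62 ± 0.14 with the drug. The lymphatic list's median was 0.05 and became -0.01 with cyclic loess and with scaling to the probe sets without a symbol, its mean was -0.12, and camera gave a downward direction (adjusted p = 0.876).

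**Figure D2:**
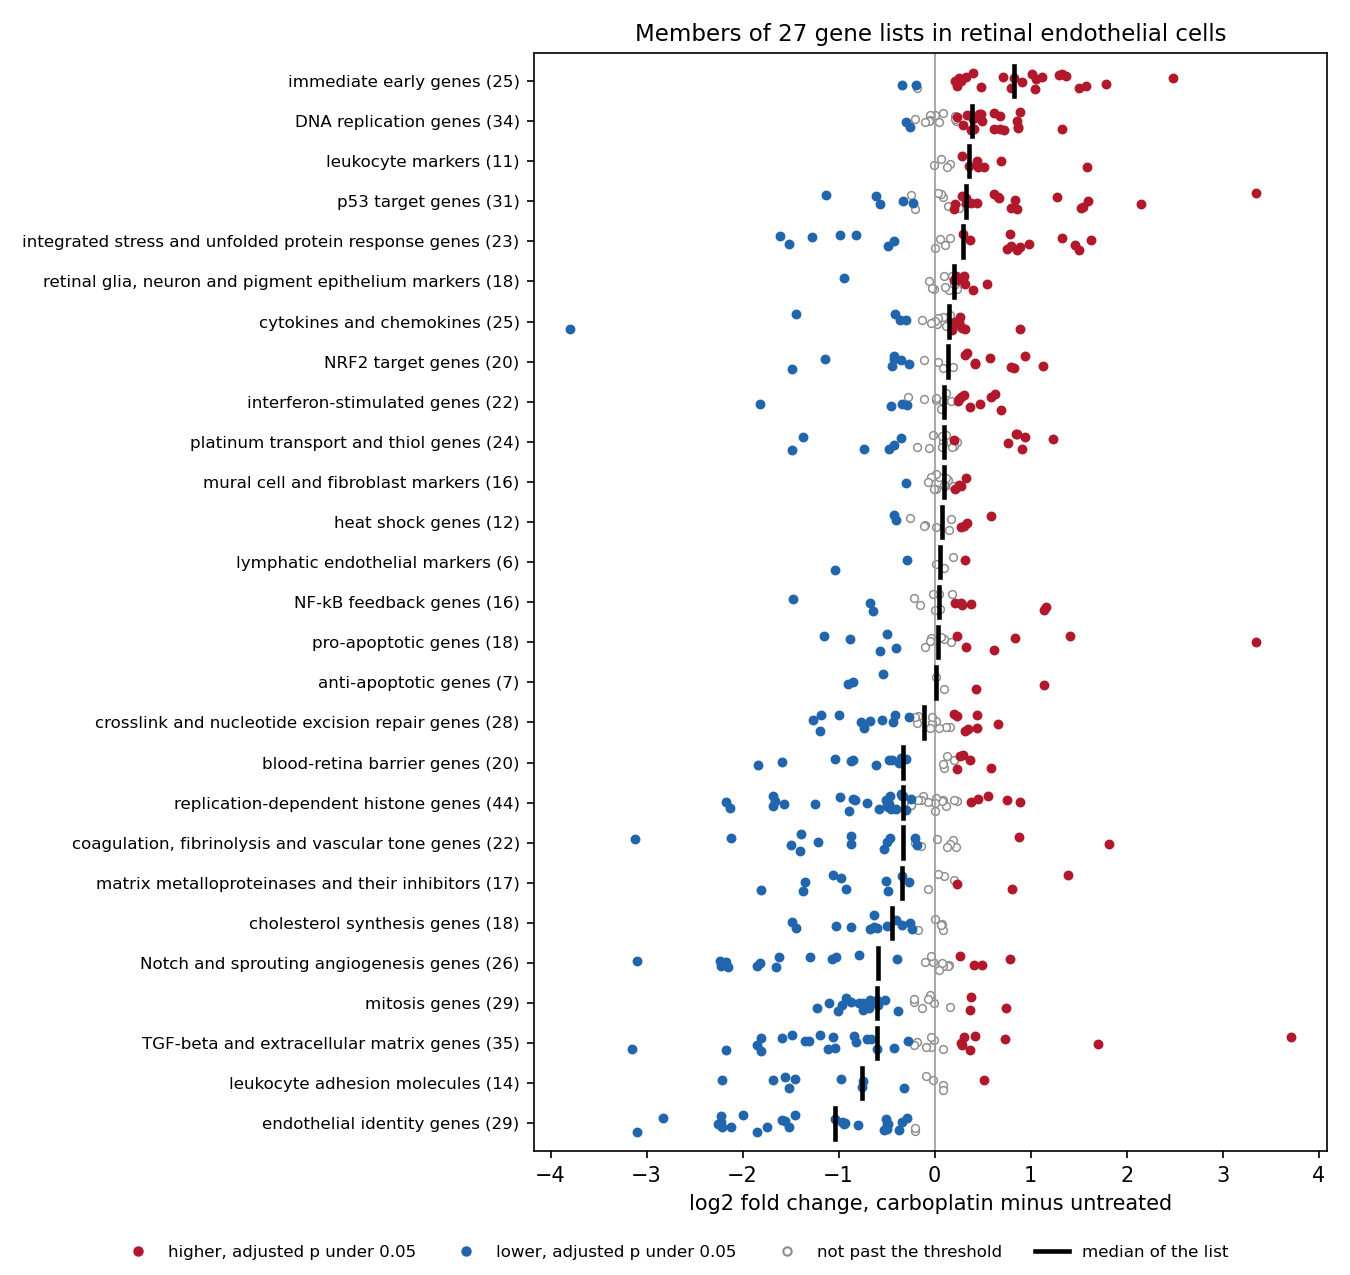
Log2 fold change, carboplatin minus untreated, of every measured member of 27 gene lists, with the number of members in parentheses, filled points for genes with an adjusted p under 0.05 and a black bar at each list's median. List medians run from -1.03 for endothelial identity genes to 0.83 for immediate early genes, and many lists hold members on both sides of 0.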

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

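The comparison of the treated group with other splits was planned, and no test in this part was chosen after its result was seen. Of the 35 ways to split the 8 arrays into 4 and 4, 1 gave as many genes past the threshold in limma, the real split itself with 9567. The highest count among the others was 0 (2720 genes at an unadjusted p under 0.05, against 10689 for the real split). The real split was thus the most extreme of the 35, and 1 of 35 is the smallest share that this test can reach. Every other split mixes treated and untreated arrays, which puts the difference between the groups into its spread. Their counts therefore do not show how many genes a random grouping of like arrays would give. The test also does not separate the drug from anything else that differed between the groups of dishes.

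Single samples that stood far from the other 3 of their group were found in 9 of 192 groups of 4 values, with 9.6 expected by chance. In carboplatin sample 2, EXOC6 was at 8.19 (others 7.60 to 7.65), TOP2A at 7.69 (others 7.40), IRF1 at 7.74 (others 7.48 to 7.51) and REV3L at 7.59 (others 7.31 to 7.35). In carboplatin sample 1, MDM2 was at 10.92 (others 11.06 to 11.07), IL6 at 6.38 (others 6.66 to 6.70) and the median of the NF-kB feedback genes at 8.07 (others 7.93). HSPA8 was at 13.74 in untreated sample 1 (others 13.71 to 13.72), and RBPMS was at 8.59 in untreated sample 2 (others 8.76 to 8.79).

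Probe sets outside the gene comparison also differed between the groups. Of 12083 probe sets without a gene symbol, 447 were at least 2-fold higher and 502 at least 2-fold lower with carboplatin, past the threshold in limma. Of 1754 probe sets with several symbols, 51 were at least 2-fold higher and 88 lower.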

How the results depend on the processing

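Protein-coding genes alone was the only setting chosen after seeing the data. All 1752 genes called at 2-fold or more kept their direction and stayed past the threshold wherever they were tested, in each of 19 settings that refit single genes without a size test, including every setting without 1 sample. Genes higher numbered 4684, and 10524 with 75th percentile scaling, 3111 with scaling to probe sets without a symbol and 2799 above the median signal, where fewer genes were tested. Genes at least 2-fold higher numbered 300, and 460 with 75th percentile scaling, 139 with treat, a stricter test, and 173 among protein-coding genes, the main difference being the small RNAs left out. Genes at least 2-fold lower numbered 1452, and 779 with treat. Both scalings add 1 constant per array, which shifts the fold changes of all genes together by 0.19 and -0.06. Lists called up numbered 4 and down 9, against 0 and 0 with an estimated correlation, 11 and 12 with fry, and 3 and 5 above the median signal. With an estimated correlation the adjusted p was 0.381 for p53 target genes, 0.282 for adhesion molecules, 0.457 for replication and 0.450 for mitosis, and above the median signal it was 0.109 for mitosis, for which the cause was not tested. Cytokines were not called in any setting. The metalloproteinase list lost its call in 7 settings.

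Without 1 sample, genes higher ranged from 3615 (without untreated sample 1) to 4973, genes lower from 4539 to 5024, 2-fold higher from 282 to 314, 2-fold lower from 1408 to 1561, lists up 4 to 4 and down 8 to 9. Of 1291 values of named genes under the alternatives, 1289 kept direction and side of the threshold, the exceptions being ICAM1 and LUM with 75th percentile scaling, and no named gene or list past the threshold turned direction. With the mean of a gene's probe sets, 3 other calls turned direction. With the sample number as a block, 4181 genes were higher and 4740 lower and 8836 of the 9567 calls were kept. The values gave no sign that the numbers pair the samples. Deviations of same-numbered samples correlated at -0.27, -0.16, -0.02 and 0.10, and 1 of 4 untreated samples matched its own number best. These correlations cannot show how the dishes were set up. Dim probe sets limit what can be seen: 17 of 25 cytokines lay below the median signal.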

Other observations

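The tests of small RNA classes and of their host genes, that of mural cell markers, those of lists other than endothelial identity against matched lists and the gene families named here, 9 of 10 tried, were chosen after the data were seen, and the other tests in this part were planned. Small nucleolar, small Cajal body and spliceosomal RNAs were mostly higher with carboplatin by counts of single genes, with no test of a class as a whole, and the medians of these classes were positive under every scaling tried. Of 61 box H/ACA small nucleolar RNAs, guides of pseudouridylation, 47 were higher and 3 lower, with a median log2 fold change of 1.58 (1.31 to 1.76 in the single treated arrays). Of 115 box C/D small nucleolar RNAs, guides of ribose methylation, 67 were higher and 11 lower (median 0.71), all 16 small Cajal body RNAs were higher (median 1.67), and of 23 spliceosomal small nuclear RNAs 18 were higher and 2 lower (median 1.06). MicroRNA genes, whose probe sets were mostly dim, had 34 of 173 higher and 21 lower, with a median of 0.10 against 0.07 for all genes, and of 0.01 against 0.03 with cyclic loess.

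Among protein families, cytosolic ribosomal proteins had 51 of 64 genes higher and none lower in limma, with a median of 0.43, where 95% of random lists matched on genomic length and signal lay between 0.13 and 0.35. Subunits of respiratory complex I had 22 of 33 higher and 4 lower (median 0.49, matched -0.08 to 0.25), and proteasome subunits 17 of 36 higher and 4 lower (median 0.21, matched -0.09 to 0.19). The 5 GIMAP genes, small GTPases of immune and endothelial cells, were all at least 2-fold lower (median -2.05, matched -0.18 to 0.44), from 1.92 lower for GIMAP6 to at least 2.82 lower for GIMAP4. Mitochondrial ribosomal proteins had 32 of 73 higher and 17 lower (median 0.15), inside the matched range of 0.06 to 0.23. RNA polymerase II with its general factors and Mediator (median -0.07, matched -0.13 to 0.12), integrins (-0.14, matched -0.52 to 0.08) and zinc finger genes (-0.03, matched 0.07 to 0.11) had medians whose direction turned with 75th percentile scaling. The RNA polymerase II group also turned with repeated quantile normalization. Genes of keratins and keratin-associated proteins had 23 of 118 higher and none lower (median 0.08, matched 0.13 to 0.21).

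Fold changes followed the genomic length of genes. Among 8757 protein-coding genes above the median signal, the shortest 10% (median 2.56 kb) had a median log2 fold change of 0.23 and the longest 10% (210 kb) of -1.13, with 1.71% and 56.7% of genes at least 2-fold lower, and Spearman's coefficient across genes, which are not independent replicates, was -0.62 (-0.62 to -0.58 in the single treated arrays). Over all 16888 protein-coding genes, dim ones included, it was weaker, at -0.45. A dependence of fold change on signal left by normalization is argued against, because the coefficient among the genes above the median signal was still -0.62 after a curve on signal was removed, and -0.67 to -0.54 within each of 5 equal classes of signal. The trend is consistent with platinum adducts that block RNA polymerase and so shorten the reach of transcription, a hypothesis that predicted a coefficient under -0.1. Loss of short-lived transcripts, which may be more frequent among long genes, was not tested and stays open. Within single gene lists, 10 of 25 passed a permutation test at an adjusted p under 0.05, all with longer genes lower, at coefficients from -0.79 for NRF2 target genes to -0.43 for TGF-beta and matrix genes, with p53 target genes at -0.55. The other 15 did not pass and ran from -0.67 for leukocyte markers to 0.50 for heat shock genes, and 3 of the 25 coefficients were positive.

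The rise of small nuclear and nucleolar RNAs has several candidate explanations. A single common factor, as a smaller pool of messenger RNA would give, predicted a difference between box H/ACA and box C/D medians under 0.5. That bound was set after the classes had been seen. Among members above the median signal the difference was 0.77 (0.54 to 0.99 in the single treated arrays), and 0.86 with all members. With all members, however, the median signal was 7.34 for box C/D and 8.37 for box H/ACA RNAs, and dim probe sets give compressed fold changes. Signal was not matched between the classes, so the difference does not decide about a common factor. For host genes, the test run first, after a check with only 2 named hosts, was the correlation of fold changes across pairs, with a bound of 0.3. Spearman's coefficient was 0.32 (bootstrap 95% interval 0.11 to 0.51), above the bound but with the bound inside the interval. A later test took the median difference between 82 small nucleolar RNAs and the genes that hold them, 0.94 (0.89 to 1.12 in the single treated arrays). It was chosen after the rise of the small RNAs had been seen, and argues only against an equal rise of the measured host transcripts. For both the correlation and the difference, a host was the measured gene whose genomic span holds the RNA, on either strand. Some pairs may therefore not be true hosts. Transcription of the host genes was not measured, so a part played by it stays open. Whether all long-lived RNA rose cannot be told apart, because the median of ribosomal protein genes, 0.43, was 0.47 to 0.71 times that of box C/D RNAs over the treated arrays, on both sides of the bound of 0.5 set beforehand. A carryover of small RNAs that differs between RNA preparations may also be possible and was not tested.

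Endothelial identity genes fell by more than randomly drawn genes of like length and signal. Their median of -1.03 lay below all 10000 lists matched on both (95% range -0.45 to 0.09). This argues against length and signal alone, although within the list longer genes fell more (coefficient -0.59). The matched lists were drawn gene by gene, whereas the list's members were correlated (estimated by camera at 0.36). Matched ranges in this part may therefore be too narrow, and counts of matched lists are not p-values. Of the 13 lists called with the preset correlation, 12 had medians outside their matched range, and coagulation genes lay inside it (-0.33, matched -0.39 to 0.11, with 489 of 10000 lists as low), which leaves length and signal open for that list. Of the 14 lists not called, 3 had medians outside their matched range, blood-retina barrier genes below it (-0.33, matched -0.20 to 0.16, with 37 of 10000 lists as low), and stress response genes (0.29, matched -0.10 to 0.25) and retinal glia, neuron and pigment epithelium markers (0.204, matched 0.025 to 0.200) above it. A lower share of endothelial RNA with mural or fibroblast RNA in its place is argued against as the whole of the fall by a median of 0.10 for the markers of those cells (0.06 to 0.13 in the single treated arrays), 3 of 16 of which another list holds, with none above 0.32. Of these markers 11 lay below the median signal, where fold changes are compressed. Among the brighter ones, named after their values were seen, COL1A1 was at 8.25 without and 8.52 with the drug and COL3A1 at 7.87 and 7.84, while RGS5, at 12.6 and 12.8, was high in both groups and decides nothing. Other explanations of the fall, a shorter half-life of these transcripts among them, were not tested. The leukocyte markers, 9 of 11 of them below the median signal of all genes, had a median of 0.35, which 4 of 10000 matched lists reached.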
